A study of Caenorhabditis elegans with 4 samples.

How the data were processed

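The samples were 4 libraries from adult hermaphrodite Caenorhabditis elegans of the strain fem-2(b245), grown at 20 degrees Celsius per the series' design text. Chromatin was fixed with EGS and formaldehyde and sonicated, and 2 libraries were made from DNA recovered with a rabbit polyclonal antibody against COH-3 (ChIP replicates 1 and 2) and 2 from input DNA. The labels give the stage as young adult with a germline, while the growth protocol describes gravid adults taken from a sucrose float. Nothing in the labels says whether the replicates came from separate worm cultures, so the difference between them may be technical, biological or both.

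The values used here were the peak positions and the peak score that the authors deposited in 3 lists. Each of the 2 ChIP replicates had its own list, called with MACS per the file contents, and 1 list, called with MACS v2 per the file contents, covered the whole series. How the whole-series list combined the replicates, and how the inputs entered the calling, is not given in the sources used here. All positions are on WormBase WS220 per the file headers, and the submitters' processing notes name ce10 and the aligner BWA. The kind of peak score is not stated either. In the per-sample lists no deposited score was under 50.03, and 36 peaks of replicate 1 and 69 of replicate 2 stood at exactly 3100, so these peaks could not be ranked against each other; 2 and 5 more peaks scored higher than 3100. The whole-series scores, from 1.34 to 205.15, are on another scale, and scores were therefore used only to rank peaks within a list. No file of the input libraries was among the peak lists used here, and these libraries entered no calculation. Sequencing depth is unknown from these lists, so an absent peak does not show absent binding, and the intervals given for shares of peaks (exact binomial, 95%) cover counting error over peaks only.

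From the lists, peaks on the 6 nuclear chromosomes were compared by overlap of at least 1 bp. A replicated region was a cluster of overlapping peaks that held at least 1 peak of each replicate, taken as the union interval and placed by its midpoint. The chance of overlap was measured with 10000 circular shifts, each moving the peaks of one replicate around each chromosome by a random amount, which keeps peak widths and spacing; these p-values are one-sided. Chromosome length was taken as the end of the last peak in any list, 100.3 Mb in all. Density on X and the autosomes was compared in bins of about 1 Mb with a two-sided permutation test (100000 permutations of the bin labels). Bins of one genome are not biological replicates, and neighbouring bins are not independent. The central part of each chromosome (the middle 33.3%) was compared with the outer parts. The outer part on the right of I, II and III and on the left of IV, V and X was compared with the opposite outer part. The design assigned these outer parts to the meiotic pairing centre, and that assignment was not checked against a published map. Both comparisons used an exact two-sided sign-flip permutation over the 6 chromosomes, in which the smallest possible p is 0.031. The 12 position tests (3 comparisons in each of 4 sets of peaks) were adjusted together by the Benjamini-Hochberg method. Positions were named by a fixed rule: the 25 replicated regions with the highest mean score percentile over the 2 replicates, ties broken by width and then position.

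Gene annotation, gene lists, noncoding gene classes and base composition had been planned and were not analysed here. The gene table at hand is for the assembly WBcel235 and the peaks are on WS220; coordinates of different builds were not combined, and the files pair no peak with a gene name. The design's rule for this case, to name regions by position, was followed. The gene lists and the tests on them were therefore not used.

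The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the overlap count was checked with bedtools 2.31.1. The functions were tested on simulated data built from the real peak widths. With 25% of the replicate 1 peaks planted in replicate 2, 23.3% were recovered above the shifted level. A planted X ratio of 0.4 was estimated at 0.38 and a planted central ratio of 2 at 1.96. In 200 simulations of a replicate 1 list with no structure, the X test called 6, the central test 5 and the overlap test 12 at the 0.05 level. The overlap test set each simulated list against the real replicate 2 list. The simulated peaks were placed independently of each other. These calls therefore do not give the error of the X test where neighbouring bins are alike, as in the real lists. Nor do they give the error of the overlap test where both lists cluster. Alternatives covered the overlap needed, the upper 50% of each list by score, each replicate alone, the whole-series list, other bins, boundaries and measures, and other placements. The main comparisons, the naming rule and most alternatives were fixed before the data were examined. The classes by score and by width were not part of that plan. Nor were the tests of the difference between the replicates in X share and central ratio, or the tests of X among the strongest peaks.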

Results

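COH-3 is a kleisin, the subunit that closes the ring of the cohesin complex, and with its close relative COH-4 it acts in meiotic chromosomes of the C. elegans germline. The strain carries a mutation in fem-2, a gene of the male-promoting branch of sex determination that is needed for spermatogenesis in hermaphrodites. The allele, b245, is temperature-sensitive, and the labels do not say whether spermatogenesis was lost at the 20 degrees Celsius used. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where COH-3 sits on the genome. The data comprised 2 COH-3 ChIP replicates, each with its own peak list, 2 input DNA libraries that were not analysed here, and 1 peak list for the whole series. Replicate 1 had 3224 peaks with a median width of 516.5 bp, which covered 2264 kb or 2.26% of the chromosomes. Replicate 2 had 4192 peaks with a median width of 326.5 bp, which covered 2067 kb or 2.06%. The whole-series list had 9642 peaks on the 6 nuclear chromosomes, with a median width of 296 bp, which covered 4394 kb or 4.38%. Read depth behind the peaks is unknown.

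The first question was which COH-3 ChIP peaks were found in both replicates. Of the replicate 1 peaks, 1048 overlapped a replicate 2 peak (32.5%, exact 95% interval 30.9 to 34.2), and of the replicate 2 peaks, 1109 overlapped a replicate 1 peak (26.5%, 25.1 to 27.8). These formed 1005 replicated regions with a median width of 690 bp, which covered 1.02% of the chromosomes. Chromosome I held 246 of them, III 206, IV 182, II 173, V 142 and X 56. Circular shifts gave 150.7 ± 13.6 overlapping replicate 1 peaks (SD over shifts), so that the observed number was 6.95 times the shifted mean. No shift reached it (highest 322, one-sided permutation p = 0.0001, the smallest that the shifts can give). The shifts do not account for background common to both libraries, for which the inputs would be needed. The overlap therefore does not by itself show that the shared peaks are COH-3 binding. In replicate 1 the share of overlapping peaks was 35.7% on the autosomes (33.9 to 37.5) and 12.5% on X (9.60 to 16.0). In replicate 2 it was 27.2% (25.8 to 28.7) and 18.1% (14.3 to 22.5). Relative to the shifted mean, which was also lower on X, overlap of replicate 1 peaks was 7.0 times on the autosomes and 6.22 times on X.

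Overlap was higher among strong peaks. In replicate 1 it went from 21.1% (16.7 to 25.9) in the lowest-scoring 10% of the list to 51.1% (45.5 to 56.7) in the highest. In replicate 2 it went from 10.0% (7.30 to 13.3) to 49.3% (44.4 to 54.2). Widths were not matched between these score classes, and the shifted level was computed for whole lists only. Wide peaks were shared to different degrees. Of the 122 replicate 1 peaks of 2 kb or more, 56.6% (47.3 to 65.5) overlapped a replicate 2 peak, while of the 96 such peaks in replicate 2, 21.9% (14.1 to 31.5) overlapped a replicate 1 peak (Fisher's exact test over peaks, two-sided, p = 2.3e-07). For narrower peaks the shares were 31.6% and 26.6%. The cut at 2 kb was not part of the plan. Among the 1152 pairs of overlapping peaks, the scores had a Spearman rho of 0.09 (bootstrap 95% interval 0.03 to 0.15, across peaks, which are not independent replicates), and of 0.15 when the upper 50% of each list by score was used.

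**Figure D1:**
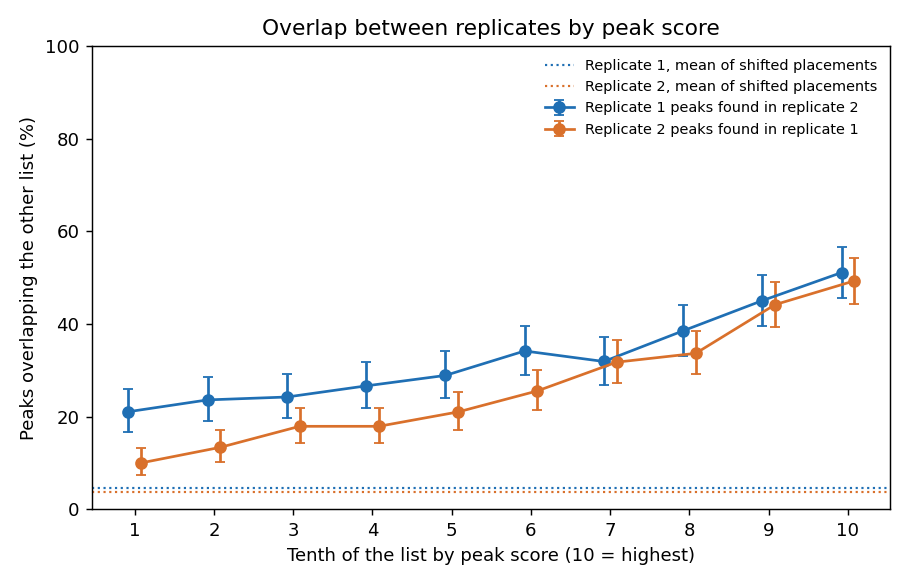
Share of the peaks of each ChIP replicate that overlap a peak of the other (y axis, percent) by position in the list ranked on peak score (x axis, 10 equal classes, 10 = highest). Points are shares, bars exact 95% binomial intervals and dotted lines the mean of the shifted placements over the whole list. Overlap is highest in the highest-scoring class, 51.1% in replicate 1 and 49.3% in replicate 2.

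The 25 replicated regions with the highest mean score percentile lay on all 6 chromosomes, with 7 on III, 6 on I, 5 on IV, 3 on V, 2 on II and 2 on X. They were wider than the replicated regions in general, with a median of 2097 bp and a range from 662 to 7651 bp. The ranking itself could favour wide regions, since a region took the highest score of its peaks and ties went to the wider region. The first was at chromosome IV 11399914 to 11401646, with a score of 3227.04 in replicate 1 and 3100 in replicate 2. The second was at III 10504967 to 10507063, with scores of 2952.63 and 3168.77. The next 4 stood at 3100 in both replicates: I 7865925 to 7873032, X 16929236 to 16935989, IV 11323038 to 11327280 and IV 11337708 to 11341436. The last 2 of these lie within an 18.4 kb stretch of chromosome IV. Another pair among the 25 lies within 10.2 kb of chromosome II, at 13817636 to 13819005 and 13826494 to 13827819. The other X region among the 25, at 1503276 to 1505326, scored 3100 in replicate 1 and 812.73 in replicate 2. The genes at these positions were not analysed here.

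Regions found in both replicates were sparser on the X chromosome than on the autosomes. Each such region needs a peak in both lists, so low X density in either list lowers the ratio of the regions. Neither list alone gave a ratio as low. Relative to the shifted mean, however, overlap of replicate 1 peaks was 6.22 times on X and 7.0 times on the autosomes. The ratio of the regions therefore does not show a depletion on X beyond the X densities of the 2 lists. Replicated regions numbered 3.16 ± 1.59 per Mb on X (SD, n = 18 bins) and 11.5 ± 6.50 per Mb on the autosomes (SD, n = 82 bins), a ratio of 0.27 (two-sided permutation test over bins, p = 1e-05, the smallest that the permutations can give; adjusted p = 6e-05). Among the autosomes, density was highest on chromosome I, at 16.3 per Mb, and lowest on V, at 6.79 per Mb. In replicate 2 alone, X had 20.3 ± 9.96 peaks per Mb and the autosomes 46.4 ± 16.7, a ratio of 0.44 (permutation p = 1e-05, adjusted p = 6e-05). In replicate 1 alone the values were 25.2 ± 9.27 and 33.7 ± 19.8, a ratio of 0.75 that did not pass the test (permutation p = 0.0825, adjusted p = 0.141). The whole-series list lay between them, with a ratio of 0.54 (permutation p = 6e-05, adjusted p = 0.00024). X carried 13.9% of the replicate 1 peaks (12.7 to 15.1) and 8.56% of the replicate 2 peaks (7.73 to 9.45). This difference itself passed a permutation test over bins that was not part of the plan (5.30 percentage points, p = 0.0158, adjusted p = 0.033 over 4 such tests).

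**Figure D2:**
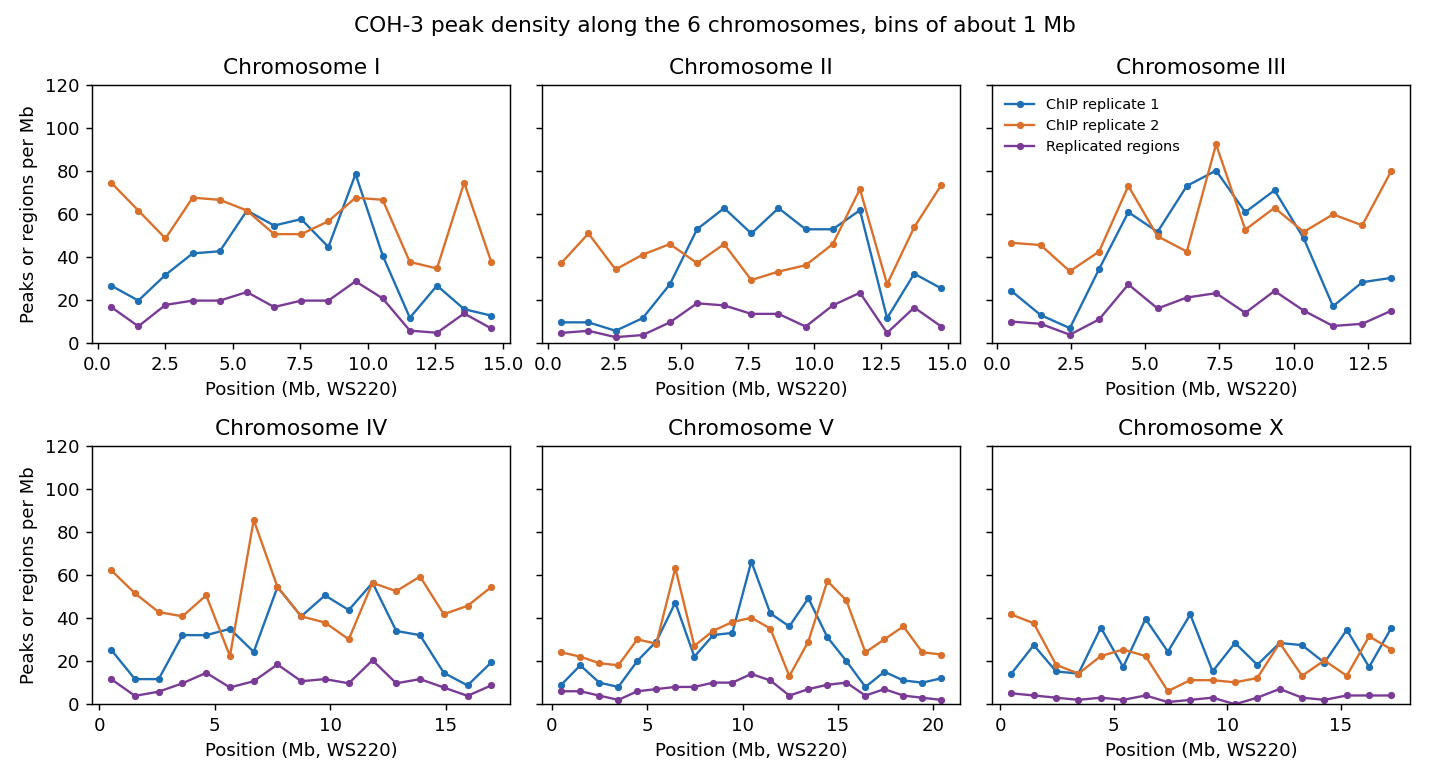
Number of peaks per Mb (y axis) in bins of about 1 Mb along each chromosome (x axis, position in Mb on WS220) for ChIP replicate 1, ChIP replicate 2 and the replicated regions. On X the replicated regions reach at most 7.1 per Mb.

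The central and outer parts of the chromosomes were compared because C. elegans autosomes have gene-dense centres, in which crossovers are rare, and repeat-rich arms. Replicate 1 had 48.7 ± 13.8 peaks per Mb in the central parts (the middle 33.3% of each chromosome) and 25.1 ± 4.76 in the outer parts (SD, n = 6 chromosomes), a ratio of 1.94. The centre was higher on 6 of 6 chromosomes, from 1.17 times on X to 2.27 times on II (exact sign-flip permutation p = 0.031, the smallest this design can give), which did not hold after adjustment (adjusted p = 0.075). In replicate 2 the values were 41.2 ± 18.2 and 44.1 ± 13.1 per Mb, a ratio of 0.93, with the centre higher on 3 of 6 chromosomes (exact permutation p = 0.438). On X, replicate 2 had 12.2 peaks per Mb in the central part and 24.3 in the outer parts. The difference between the replicates in this ratio had the same sign on 6 of 6 chromosomes (mean log2 difference 1.13, exact sign-flip permutation p = 0.031, adjusted p = 0.033 over 4 tests). The adjusted values of 0.075 and 0.033 come from the same p in families of different size. Replicated regions were denser in the centre on the 5 autosomes and less dense there on X, with 13.2 ± 6.96 against 9.11 ± 3.97 per Mb, which did not pass the test (ratio 1.45, exact permutation p = 0.0625, adjusted p = 0.125).

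**Figure D3:**
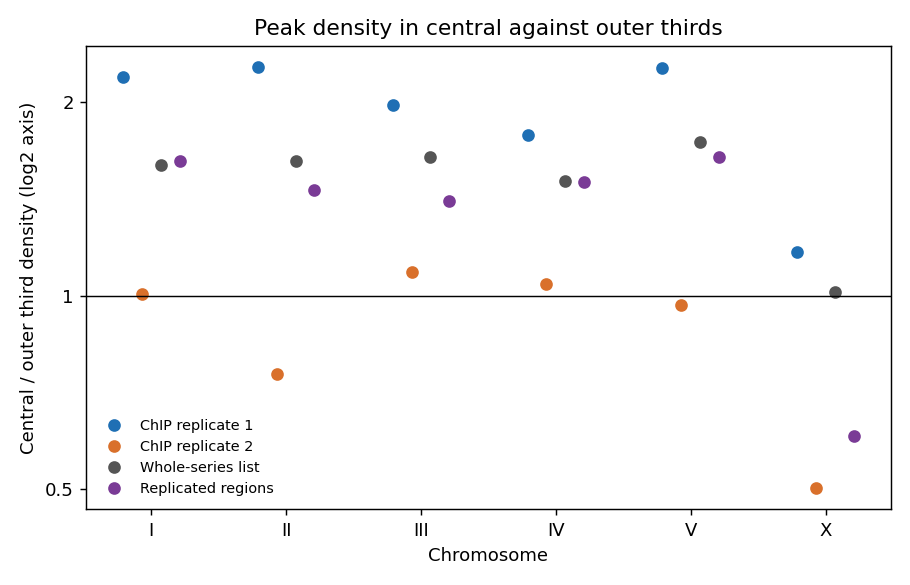
Ratio of peak density in the central part of the chromosome (the middle 33.3%) to that in the outer parts (y axis, log2 scale) for each chromosome (x axis) in the 3 peak lists and the replicated regions; 1 point per chromosome and set, and the line marks equal density. Replicate 1 lies above replicate 2 on 6 of 6 chromosomes, and on X the replicated regions have a ratio of 0.60.

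Meiotic pairing centres are the chromosome regions near one end through which homologues pair and start synapsis. The outer part that the design assigned to the pairing centre had 9.39 ± 4.41 replicated regions per Mb and the opposite outer part 8.83 ± 4.82 (SD, n = 6 chromosomes), a ratio of 1.06 (exact sign-flip permutation p = 0.75, adjusted p = 0.812). The part so assigned was denser on chromosomes II, at 14.1 against 5.50 per Mb, and III, at 13.9 against 12.4. It was less dense on I, at 10.5 against 16.5, and X, at 3.22 against 4.06, and equal on IV and V. The difference between the ends varied between chromosomes with an SD of 4.72 per Mb, so that a small difference was not detectable. Since the assignment of ends was not checked, these values cannot show whether density differs at the pairing centres.

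The whole-series list held many peaks that neither replicate list contained. Of its 9642 peaks, 1019 overlapped a peak of both replicates (10.6%, 9.96 to 11.2), 2293 one of replicate 1 alone (23.8%), 2387 one of replicate 2 alone (24.8%) and 3943 one of neither (40.9%, 39.9 to 41.9). Peaks found in both had a median whole-series score of 25.91, and those found in neither 4.4. In the highest-scoring 10% of the list, 59.7% (56.5 to 62.8) were in both and 0.62% (0.23 to 1.35) in neither. Of the replicate 1 peaks, 97.8% were in the whole-series list, and of the replicate 2 peaks, 85%.

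The highest-scoring whole-series peaks included more X peaks than the rest of the list, although X had the fewest peaks. X held 16 of the 25 highest-scoring peaks (64%, 42.5 to 82.0) and 30 of the highest 100 (30%, 21.2 to 40.0), against 10.2% of the other 9542 peaks (Fisher's exact test over peaks, two-sided, p = 5.37e-08, adjusted p = 3.22e-07 over 12 such tests). Among the highest 500 it held 71 (14.2%, 11.3 to 17.6; Fisher's exact test, adjusted p = 0.0203). These cuts of 25, 100 and 500 were chosen after the values were seen. The highest 7 were X 14525150 to 14526621 (whole-series score 205.15), X 6295919 to 6297218 (201.77), X 8035719 to 8037111 (200.59), X 11093411 to 11094796 (200.12), X 2996264 to 2997636 (192.83), X 16055871 to 16056981 (191.69) and X 9465247 to 9466492 (187.14). The 30 X peaks had a median width of 1108.5 bp and were spread from 142824 to 17544739, with a median distance of 538 kb between neighbours. They overlapped a replicate 1 peak in 27 cases and a replicate 2 peak in 24. Their median score percentile was 98.5 in the replicate 1 list and 81.5 in the replicate 2 list, over those with a peak there. For the 70 autosomal peaks among the highest 100, the medians were 93.9 and 97. Within the lists, X made up 25% of the 100 highest-scoring replicate 1 peaks and 13.5% of the others (Fisher's exact test, adjusted p = 0.0112). For the highest 500 of replicate 1 the shares were 16.2% and 13.4%, which did not pass Fisher's exact test (adjusted p = 0.21). The highest 25 could not be told from the other peaks tied at 3100, and of the 38 replicate 1 peaks at or above that score, 11 were on X (28.9%, 15.4 to 45.9), as were 10 of the 74 such peaks of replicate 2 (13.5%, 6.68 to 23.5). In replicate 2 the shares for the highest 100 were 11% and 8.50% (Fisher's exact test, adjusted p = 0.618).

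**Figure D4:**
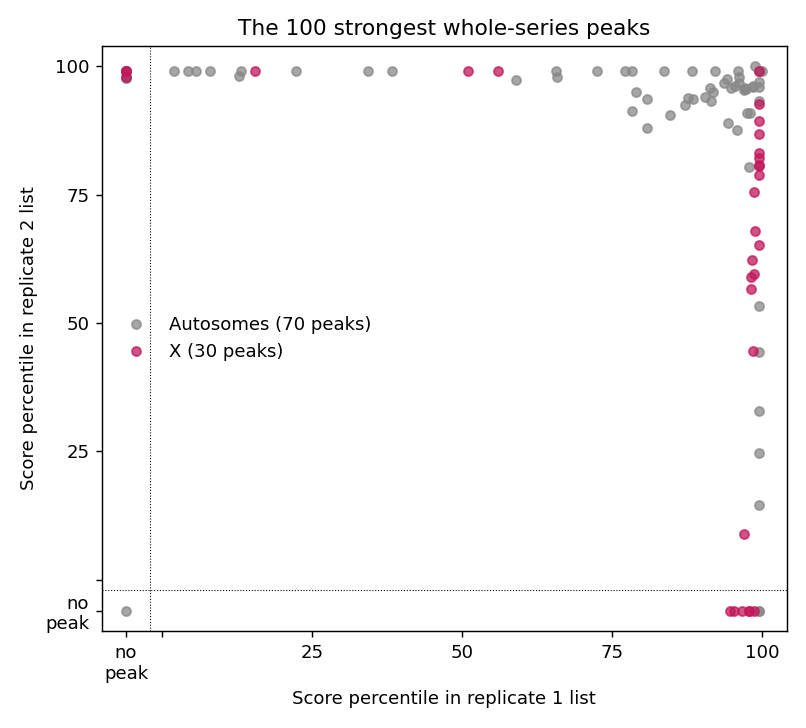
Score percentile of the overlapping peak in the replicate 1 list (x axis) and in the replicate 2 list (y axis) for the 100 highest-scoring whole-series peaks, 30 on X and 70 on autosomes; peaks with no overlapping peak in a list are drawn at "no peak". Most X peaks stand at the right edge, above the 94th percentile of replicate 1, and are spread over the replicate 2 range.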

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

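The whole-series list contained a single peak on the mitochondrial DNA, from base 1 to 13312, with a score of 93.08, which 0.83% of the chromosomal peaks exceeded. It was picked out because it lies outside the nuclear chromosomes that were compared, and neither replicate list holds a mitochondrial peak.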

How the results depend on the processing

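Of 35 alternative settings over 7 results, 27 kept the direction and the side of the threshold or stayed within the set limits; 6 of the 35 were chosen after seeing the data. The overlap between replicates stayed above the shifted placements in 5 of 5 settings. It was 18.8% of replicate 1 peaks when 50% of both peaks had to be shared and 41.5% when peaks within 1000 bp counted. The fold over the shifted mean depended on the setting, at 20.3 and 3.85 in these 2 cases against 6.95 in the main setting. The number of replicated regions fell from 1005 to 606 with 50% reciprocal overlap and to 473 in the upper 50% of each list by score. The share of whole-series peaks in both lists, 10.6%, became 5.67% with reciprocal overlap and 9.81% in the upper 50%. Spearman's rho between the scores of overlapping peaks, 0.09, was 0.15 in the upper 50% of each list. The X to autosome ratio was 0.27 for the replicated regions, 0.44 for the replicate 2 list and 0.75 for the replicate 1 list. Replicate 1 alone, at 0.75, did not pass the test, and the other 8 settings kept the ratio past the threshold. The central to outer ratio of 1.45, which did not pass, ranged from 0.93 to 1.94 when one replicate was left out: with replicate 2 alone it turned below 1, and with replicate 1 alone it passed the unadjusted test, as did the whole-series list at 1.55. The cause of these changes was not tested beyond the comparison of the replicates. The comparison by assigned pairing centre side stayed short of the threshold in 8 of 8 settings. No paired analysis was possible because the inputs that share replicate numbers with the ChIP libraries have no values here and a peak list gives no value per region for them. The planned settings on annotation, gene lists, noncoding genes and base composition were not run. What limits these results is that read depth is unknown, that 36 peaks of replicate 1 and 69 of replicate 2 tie at a score of 3100 and that only 2 ChIP libraries exist.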

Other observations

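Each of the 3 lists had a peak that started at base 1 on 6 of 6 chromosomes, with scores from 131.6 to 910.98 in replicate 1, from 431.01 to 2288.1 in replicate 2 and from 16.67 to 93.33 in the whole-series list. These left ends are therefore counted among the replicated regions on 6 of 6 chromosomes. Whether they reflect background was not tested, since the inputs have no values here. The right ends could not be compared in this way, since the length of each chromosome was taken from the last peak of any list. That last peak was a whole-series peak on 6 of 6 chromosomes, with scores from 35.88 to 100.56. The right end of chromosome I, where the large ribosomal RNA genes lie in tandem repeats, carried an 11067 bp peak at 15060286 to 15071352 with a score of 3100 in replicate 2, while the last replicate 1 peak on that chromosome ended at 15041772 with a score of 122.47.

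The tests on the overlap of the replicates, on calling depth for the X share and on the strong X peaks were chosen after the values they rest on had been seen at least in part; the test on calling depth for the central parts was set before its result was seen.

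The low overlap between the replicates, 32.5% of replicate 1 peaks, may have several sources. For the next 2 tests a bar of 90% overlap was set after the values had been seen at least in part. Overlap rose with score in both lists, which leaves a part for weak peaks near the calling threshold. Weak replicate 1 peaks do not account for the low overlap alone. Of the highest-scoring 10% of replicate 1, 51.1% overlapped replicate 2, and the upper end of the interval was 56.7%. This test used the replicate 1 score only. A strong replicate 1 peak may lie just under the calling threshold in replicate 2, so a threshold effect in replicate 2 remains open. Peak edges placed differently do not account for the low overlap alone either: 41.5% of replicate 1 peaks lay within 1000 bp of a replicate 2 peak (39.8 to 43.2). A difference between the worm preparations, in the immunoprecipitation or in the identity of a library remains open, since the labels give no date or batch and the input libraries have no values here.

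The chromosome pattern differed between the replicates, with more of the replicate 1 peaks on X and in the central parts of the chromosomes. Calling depth, in the sense of the number of peaks called in a list, is a candidate explanation. It predicts that the difference fades when equal numbers of strong peaks are compared. Among the 1000 highest-scoring peaks of each list, the X share still differed by 5.5 percentage points (13.2% and 7.7%, permutation p over bins = 0.033, adjusted p = 0.033). The central to outer ratio was 1.84 and 0.89, a mean log2 difference of 1.08 with the same sign on 6 of 6 chromosomes (exact sign-flip permutation p = 0.031, the smallest possible). Both values argue against calling depth in this sense as the whole explanation. Equal numbers of peaks do not equalise read depth, which is unknown, so the part of read depth could not be decided. A difference in tissue make-up, such as the share of germline nuclei, or in background between the libraries remains open, and the design names no group that would separate them.

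The strong X peaks of the whole-series list might be the signal of one library. Of the 30 X peaks among the 100 strongest, 80% (61.4 to 92.3) overlapped a replicate 2 peak, against 95.7% (88.0 to 99.1) of the 70 autosomal peaks. A peak in both lists was present for 21 of the 30, while 6 had none in replicate 2 and 3 none in replicate 1. Any overlapping replicate 2 peak counted, down to a score percentile of 8.84. The overlap therefore cannot decide whether 1 library carried most of the signal of these X peaks. Their rank does lean on replicate 1: of the 21 X peaks found in both lists, 17 had the higher percentile there, against 18 of 60 autosomal peaks (Fisher's exact test over peaks, p = 7.46e-05, with peaks at or above 3100 in both lists counted as not higher), and X made up 11% of the 100 strongest replicate 2 peaks and 8.50% of the others (adjusted p = 0.618). Whether these sites coincide with recruitment sites of the X-chromosome dosage compensation complex, which contains a condensin, was not tested, since the coordinates of those sites were not used here. It also remains open whether the replicate 1 library holds DNA recovered with COH-3 alone, and whether the background is locally high, for which the inputs would be needed.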
